A study of Rattus norvegicus with 2 samples.

How the data were processed

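Liver RNA of Sprague Dawley rats was measured on 2 one-colour (Cy3) Agilent oligonucleotide arrays, 1 for animals given sodium chloride and 1 for animals given senecionine, a hepatotoxic pyrrolizidine alkaloid, by the intragastric route at 35 mg/kg. Livers were taken 36 h after dosing. Per the series' design text, tissue of 3 animals was pooled for each group, so each array reports a pool and the spread between animals cannot be estimated. That text also speaks of 2 independent experiments, which was read here as the 2 arrays, since it names the control and the treated group in explanation. Both arrays came from 1 slide scan, per the file headers, and slide or scan therefore do not separate the groups.

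The spot intensity values were made by the authors with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The software subtracted the background, removed spatial and multiplicative trends within the array and gave each spot an error. The deposited intensity values were not scaled between arrays. The authors' series table holds deposited log2 values for 7404 probes. Its scaling is not given in the sources used here. Its smallest absolute log2 difference between the columns is 1.0001, so it is a list selected at 2-fold. Its columns have medians of 6.03 for control and 6.10 for senecionine, and its direction was found by setting it against the scanner signals. All 7355 of its probes that were also compared here differed in the same direction (Pearson r = 0.994 across probes, which are not independent replicates).

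For the present values, log2 of the processed signal was taken, each array's 75th percentile over non-control spots was subtracted, and spots of 1 probe were averaged on the log2 scale. Control spots were left out, as were spots with a non-uniformity or population outlier flag, 522 on the control array and 497 on the senecionine array. No non-control spot was saturated. This left 40516 probes. The scanner files name probes by accession only, so gene symbols were taken by matching unversioned RefSeq transcript accessions to the RefSeq gene table of assembly GRCr8. That matched 17250 probes to 13667 genes and left 23266 probes without a name here. The array was designed on another build, so no coordinates are given. A gene was called measured where at least 1 probe was well above background on both arrays, and its brightest such probe represented it. Genes well above background on 1 array only were given a lower bound on their fold, the bright signal against the higher of the dim probe's own signal and the lowest signal well above background on that array. Probes of near-identical gene families (Cyp2c, Cyp2a, Cyp4a, Ugt2b, Gst, Sult, Ces, Mup and globin genes) can hybridise to each other's transcripts, and values of single members are uncertain for that reason.

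With 1 array per group no test was made and no p-value is given. Genes were counted by size, at a log2 ratio (senecionine minus control) of at least 1 in either direction. The error beside a log2 ratio is Agilent's spot error carried to the ratio. It is technical error within the arrays. Its median over the measured genes was 0.21. Probes spotted repeatedly varied by a median log2 SD of 0.13 on the control array (140 probes with every spot well above background) and 0.11 on the senecionine array (183 probes). In data simulated from the control array with these spot errors, 1 of 7603 unchanged genes passed the 2-fold rule, and all 50 genes changed by 1.5 on the log2 scale were recovered. Apart from the set changes, the simulated arrays differed by spot error only and shared their detection. The simulation thus checks the counting and gives no rate of false calls between arrays, pools or animals. The number of arrays limits the precision.

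The groups come from the sample titles. The rules, 33 gene lists and named genes were fixed before the data were examined: the 10 highest and 10 lowest log2 ratios, the 3 highest bounds on each array, up to 4 members per list with the largest absolute ratio, and 17 genes given in any case, of which Cyp3a1 and Stab2 have no probe that could be named here and 1 is not reported here. For each list, the median log2 ratio was placed among those of 10000 random lists of measured genes matched on mean signal in 20 bins, as a description of these arrays. Markers of brain, other tissues and the Y chromosome were listed after the data were first examined. The brain markers left out the neural genes already seen. Alternatives were other scalings (median, quantile, cyclic loess), normexp background correction with offset 50, other filters, other probe rules, other fold thresholds and the authors' values. The planned normexp correction on mean signals used the median spot signals, since the files hold no mean signals. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.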

Results

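To ask which liver transcripts differ 36 h after senecionine, a pyrrolizidine alkaloid of ragwort-type plants that liver enzymes convert to reactive pyrroles, RNA pooled from 3 treated rats was compared with RNA pooled from 3 rats given sodium chloride. Each pool was hybridised to 1 array, so there are no replicates, and each difference below is between 2 arrays. Of 43379 non-control spots per array, 44.4% were well above background on the control array and 64.1% on the senecionine array. The 75th percentile of processed signal was 101 intensity units on the control array and 134 on the senecionine array. The control array was the noisier of the pair, with a standard deviation of negative control spots of 3.39 against 2.0 intensity units.

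Among genes well above background on both arrays, the highest ratio after senecionine was that of Slpi and the lowest that of Mt3, a metallothionein known from brain. Slpi, a secreted inhibitor of leukocyte proteases, was 95.3-fold higher (log2 ratio 6.57 ± 0.24, spot error). The myeloid calcium-binding proteins S100a9 and S100a8 were 92.2-fold and 77.4-fold higher. The stress transcription factor Atf3 was 65.1-fold higher, the iron-carrier protein Lcn2 52.7-fold, the neutrophil attractant Cxcl1 50.6-fold, the lactate exporter Slc16a3 41.9-fold, the cell cycle inhibitor Cdkn1a 41.4-fold, the monocyte attractant Ccl2 35.8-fold and the carbonic anhydrase Car4 30.5-fold. At the other end, the male-specific cytochrome Cyp2c11 was 104-fold lower (log2 ratio -6.70 ± 0.20) and Obp3, an alpha-2u globulin, 110-fold lower. The other 8 of the 10 lowest were Mt3 (386-fold lower), Scg5 (118-fold), Caly (106-fold), Camk2b (96.7-fold), Mbp (86.1-fold), Cx3cl1 (61.0-fold), Resp18 (56.7-fold) and Fbll1 (54.9-fold), most of them known for expression in the nervous system. Probes disagreed for Camk2b, whose other probe gave a log2 ratio of 0.135, and in size for Scg5, Mbp and Cx3cl1, whose other probes gave -2.33, -4.95 and -2.48.

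Among 7803 genes measured on both arrays, 876 were at least 2-fold higher and 1379 at least 2-fold lower after senecionine, and 5548 lay within 2-fold. At 4-fold, 213 were higher and 361 lower. Higher genes made up 38.8% of those past 2-fold, but 60.5% when a gene needed detection on only 1 array and 57.8% with the authors' values. The authors' table is not limited to probes detected on both arrays. Of its 7355 probes compared here, 4826 were well above background on both. The median log2 ratio of all measured genes was -0.14. The log2 signals of the arrays correlated with Pearson r = 0.885 across genes, which are not independent replicates.

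**Figure D1:**
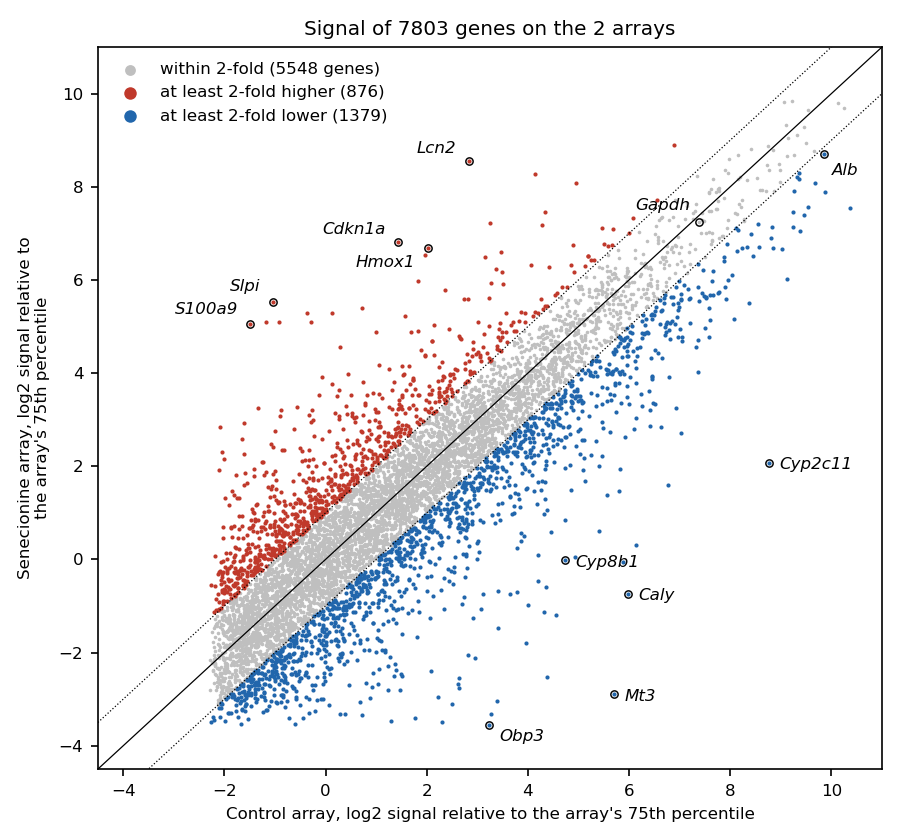
Log2 signal of 7803 genes on the control array (x axis) and the senecionine array (y axis), each relative to its array's 75th percentile, with 1 point per gene. The solid line marks equal signal and the dotted lines 2-fold. The 876 higher genes are red and the 1379 lower genes blue, with Slpi and S100a9 far above the line and Cyp2c11, Caly, Mt3 and Obp3 far below it.

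Targets of p53, the transcription factor of the DNA damage response, were higher as a group. Of 19 measured members of the list, 13 were at least 2-fold higher and none was at least 2-fold lower. A further 5 were detected on the senecionine array only. Such detection was common, at 2612 genes against 177 on the control array only, so here and below it gives a list no direction. The list's median log2 ratio of 1.71 lay at percentile 100 of random lists matched on signal. Beside Cdkn1a, the secreted stress factor Gdf15 was 16.3-fold higher, Gadd45a 9.73-fold, Tp53inp1 9.49-fold, the cyclin Ccng1 8.38-fold (log2 ratio 3.07 ± 0.21) and Mdm2, the ubiquitin ligase of p53, 6.52-fold (2.70 ± 0.21).

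Stress and immediate early genes stood on the same side. Of 17 measured immediate early genes 13 were at least 2-fold higher and none lower, with a median of 1.59. Ccn2 was 10.3-fold, Klf6 6.41-fold and Myc 6.29-fold higher beside Atf3. Heat shock genes were at least 2-fold higher in 12 of 21 cases and lower in none, led by Hspb1 (10.2-fold), Cryab (9.21-fold) and Hsph1 (8.37-fold). Endoplasmic reticulum stress genes were higher in 11 and lower in 2 of 26. Ppp1r15a was 5.91-fold, the asparagine synthetase Asns 5.63-fold, and Creld2 5.18-fold higher. In the list of metal and hypoxia response genes, 10 of 21 were higher, among them the oxygen sensor enzyme Egln3 (14.3-fold), the vasodilator peptide Adm (12.8-fold) and the collagen hydroxylase P4ha1 (7.52-fold). The 1 lower member was Mt3.

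Targets of NRF2, the regulator of antioxidant defence, had no common direction. Of 26 measured, 5 were at least 2-fold higher and 2 lower, and none was lower with cyclic loess, quantile normalization or normexp correction. The median of -0.12 turned to 0.11, 0.12 and 0.03 with these. The haem-degrading enzyme Hmox1 was 25.3-fold higher (log2 ratio 4.66 ± 0.20), Gstm3 4.34-fold and Txnrd1 2.17-fold (log2 ratio 1.12, other probe 0.45). Nqo1 had a log2 ratio of -0.06 ± 0.21, within its spot error, and Gclc, which limits glutathione synthesis, one of -0.57 ± 0.21. The reductase Akr1b8, well above background on the senecionine array only, was at least 40.1-fold higher.

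Drug-metabolising genes were lower as a group. Of 46 measured cytochrome P450 and flavin monooxygenase genes, 29 were at least 2-fold lower and 1 higher (3 higher with quantile normalization or cyclic loess), with a median log2 ratio of -1.30 at percentile 0.0 of random lists. After Cyp2c11 came Fmo1 (10.3-fold lower), Cyp17a1 (9.78-fold) and Cyp2a2 (6.54-fold). Cyp3a2, of the family that activates pyrrolizidine alkaloids, was 2.30-fold lower (-1.20 ± 0.20). Cyp1a1 was not well above background on the control array and was at least 2.03-fold higher after senecionine. Conjugation and transport genes were lower in 22 and higher in 1 of 38. Gstm7 had a log2 ratio of -3.46, the estrogen sulfotransferase Sult1e1 was 10.2-fold and Ces1d 5.83-fold lower, whereas the carboxylesterase Ces2c was 18.8-fold higher.

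Bile acid genes followed the same direction, with 15 of 25 at least 2-fold lower and 2 higher (median -1.39). Cyp8b1, the sterol 12-alpha-hydroxylase, was 27.0-fold lower, the bile salt uptake carrier Slc10a1 10.1-fold, the nuclear receptor Nr0b2 9.71-fold and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 4.40-fold lower (-2.14 ± 0.20). The basolateral export pump Abcc3 was 6.54-fold higher.

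Most lists of intermediary metabolism were also lower. In the list of urea cycle and amino acid metabolism, 30 of 37 genes were at least 2-fold lower and none higher (median -1.68), with Sds 10.6-fold, Cbs 9.51-fold, Gnmt 8.74-fold and Bhmt 7.08-fold lower. Fatty acid oxidation genes were lower in 18 and higher in 3 of 33. Hadh was 7.34-fold and the ketone body enzyme Bdh1 6.97-fold lower, while the hormone Fgf21 was 7.12-fold higher. Fatty acid synthesis genes were lower in 11 and higher in 1 of 20, with the desaturases Scd and Fads2 7.35-fold and 6.08-fold lower. Cholesterol synthesis genes were lower in 7 of 23 (median -0.70), but in 3 with normexp correction, where 1 was higher. Among them Hmgcs1 was 4.32-fold lower, with a log2 ratio of -0.89 on its other probe. Glucose metabolism genes split, with 10 lower and 5 higher of 20. The glucose-6-phosphatase G6pc1 was 13.7-fold and the glucokinase regulator Gckr 12.9-fold lower, and the binding protein Igfbp1 17.6-fold and the pyruvate kinase Pkm 7.27-fold higher.

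Genes of both lobular zones were among the lower ones. Of 25 measured pericentral genes 11 were at least 2-fold lower and 2 higher, and of 22 periportal genes 14 were lower and none higher, though 8 under quantile normalization. Notum was 11.1-fold, Gulo 8.62-fold and Cyp2e1 4.52-fold lower on the pericentral side, and on the periportal side Hal was 5.74-fold lower and Ass1 had a log2 ratio of -2.81. Many of these genes also count in other lists here. Hal, Ass1, Sds and Cps1 are in the urea cycle list, Alb is in the secreted protein list and Cyp2e1 in the cytochrome P450 list. The zonal counts are therefore not a separate result. Whether the zones differ was not tested.

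Secreted proteins and coagulation factors made by hepatocytes were lower. In the list of secreted proteins 17 of 23 were at least 2-fold lower and none higher (median -1.46), and under quantile normalization 10 were lower and 1 higher. Serpina6, the corticosteroid carrier, was 18.3-fold lower, Igfals 8.96-fold, Apoa2 6.77-fold and Alb 2.20-fold (-1.14 ± 0.20). Of 16 coagulation genes 9 were lower and none higher, with 6 lower under quantile normalization. F12, Serpind1 and protein C (Proc) were 4.12-fold, 4.05-fold and 3.80-fold lower. The list of growth hormone regulated and sex-biased genes had the lowest median of the 33 lists, -2.03, with 21 of 26 genes at least 2-fold lower and none higher. Beyond Obp3 and Cyp2c11 it held Hsd17b2 (36.0-fold lower) and Akr1c1 (29.2-fold lower).

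**Figure D2:**
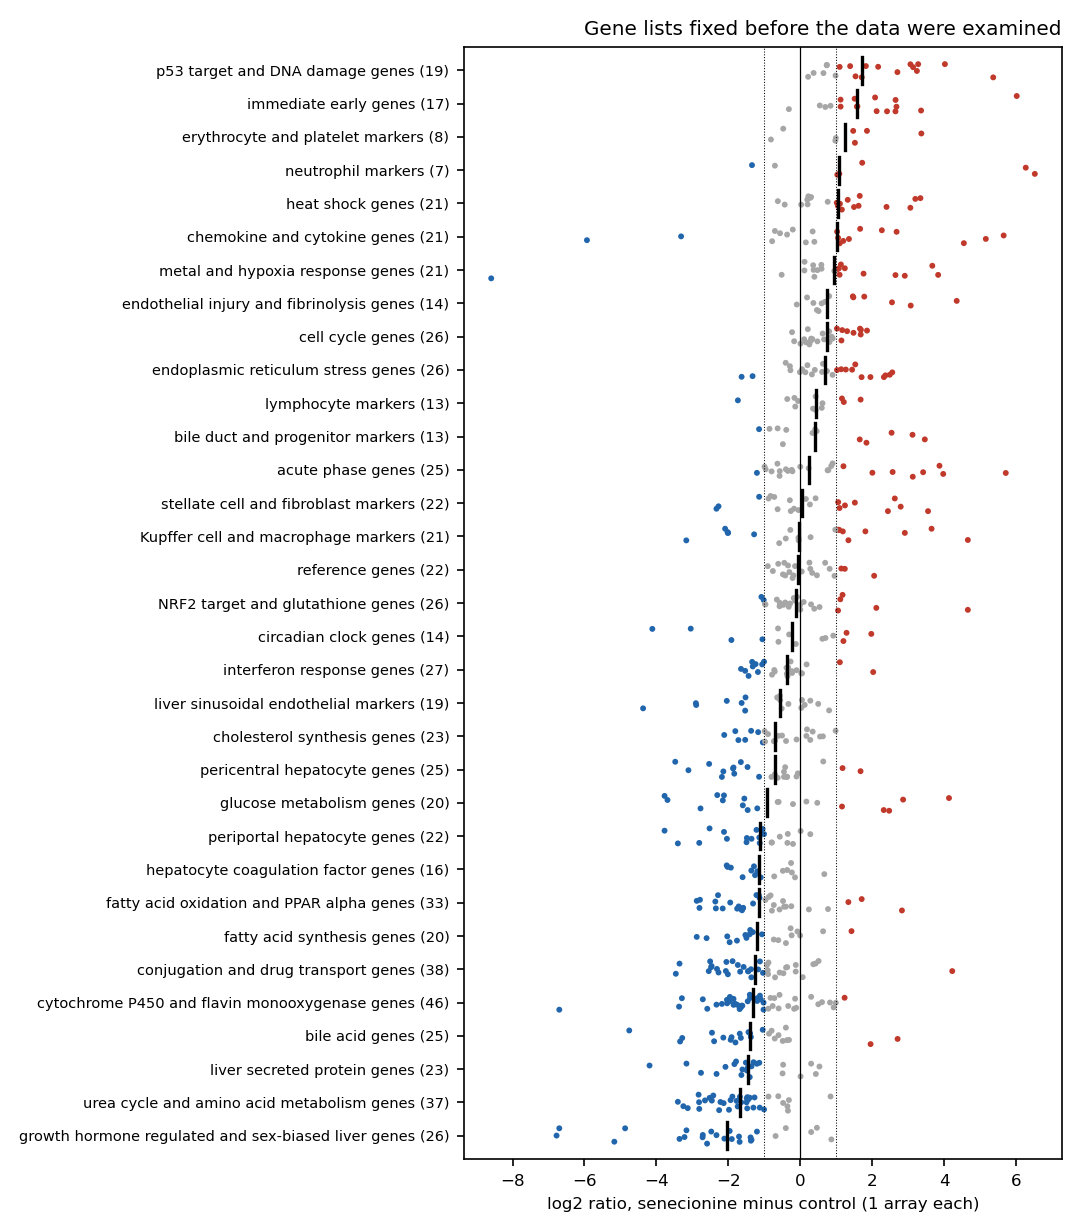
Log2 ratio (x axis, senecionine minus control) of each measured member of the 33 gene lists, with 1 point per gene, the number measured in brackets and a black bar at the list's median. Red points are at least 2-fold higher and blue points at least 2-fold lower; medians run from 1.71 for p53 targets to -2.03 for growth hormone regulated and sex-biased genes.

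Lists of inflammation differed in how many members were higher. Acute phase genes were higher in 8 and lower in 1 of 25, with 16 within 2-fold, and beside Lcn2 the protease inhibitor A2m was 15.8-fold (3.98 ± 0.20), and Lbp 14.7-fold higher, and Cebpd had a log2 ratio of 3.42. Chemokine and cytokine genes were higher in 11 and lower in 2 of 21, with 9 more detected on the senecionine array only, and higher in 7 with normexp correction. Ccl7 was 23.5-fold higher, and Cxcl2 at least 37.4-fold. Of 7 measured neutrophil markers 5 were higher and Prtn3 2.53-fold lower, or 3 higher and none lower with normexp correction. Itgb2 was 3.31-fold higher. Interferon response genes were lower in 9 and higher in 2 of 27, or 3 and 1 with normexp background correction. The median of this list lay at percentile 13.43 of random lists matched on signal, so the list as a whole was not set apart. Usp18, Ifit1 and Ifi44 were 3.13-fold, 2.89-fold and 2.70-fold lower and Rsad2 4.09-fold higher. The other probe of Usp18 gave a log2 ratio of -0.29, within 2-fold. Of 13 lymphocyte markers 3 were higher, Cd3g (3.21-fold), Cd48 and Cd8b, and Gzma was 3.32-fold lower. With normexp correction none was higher. The lymphocyte median lay at percentile 93.63 of random lists, and the acute phase, chemokine and neutrophil medians at 99.6, 100 and 99.45.

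Macrophage markers parted. Of 21 measured, 8 were at least 2-fold higher and 6 lower, and 4 more were detected on the senecionine array only. The 8 include Hmox1, given above with the NRF2 targets. The Kupffer cell lectin Clec4f was 8.98-fold lower, whereas Gpnmb and Lgals3, known from recruited and phagocytic macrophages, were 12.6-fold and 7.52-fold higher. Sinusoidal endothelial markers were lower in 7 of 19 and higher in none (median -0.56), with 5 more detected on the senecionine array only, or lower in 4 with normexp correction. Dnase1l3 was 20.7-fold, the mannose receptor Mrc1 7.47-fold, the VEGF receptor Kdr 7.42-fold and Oit3 4.12-fold lower. Endothelial injury and fibrinolysis genes were higher in 6 and lower in none of 14. The protein C receptor Procr was 20.5-fold, the protease inhibitor Timp1 8.43-fold and Angpt2 5.87-fold higher. Of 8 measured erythrocyte and platelet markers 4 were higher and none lower, among them the platelet factor Pf4 (10.3-fold) and beta-globin Hbb (3.63-fold). Stellate cell and fibroblast markers were higher in 8 and lower in 3 of 22 (median 0.06). Dcn was 11.8-fold, Tagln 6.94-fold, Vim 6.20-fold and Des 5.43-fold higher. The 3 lower were Lrat, Hhip and Sparc, at log2 ratios of -2.33, -2.27 and -1.14. Bile duct and progenitor markers were higher in 5 and lower in 1 of 13, led by Tnfrsf12a (11.1-fold), Krt8 (8.73-fold) and Epcam (5.83-fold). Spp1, of the same list, was well above background on the senecionine array only and at least 106-fold higher. Among random lists, the medians of macrophage, stellate cell and bile duct markers lay at percentiles 72.78, 88.36 and 97.06. Sinusoidal endothelial markers lay at 3.5, endothelial injury genes at 99.84, and erythrocyte and platelet markers at 99.99.

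Cell cycle genes were higher in 9 and lower in none of 26 (median 0.74), and higher in 5 with normexp correction. Tyms, Ccna2 and Cdc25b were 3.23-fold, 3.21-fold and 3.17-fold higher. Rrm1 was 3.63-fold higher on its brighter probe, with a log2 ratio of 0.18 on the other. Circadian clock genes went both ways, 4 lower and 3 higher of 14. Dbp was 17.3-fold and Nr1d1 8.25-fold lower, and Wee1 3.94-fold higher. Of 22 reference genes 3 were at least 2-fold higher and none lower (6 under quantile normalization or cyclic loess). Gapdh had a log2 ratio of -0.14 ± 0.20, within its spot error, but Actb one of 1.15 ± 0.20 and Ywhaz one of 2.06 ± 0.20.

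Because genes known from brain were among the lowest, markers of other tissues were then looked up, chosen without the neural genes already seen. Of 54 named markers of neurons, oligodendrocytes and astrocytes, 34 were well above background on the control array. Among all 13667 named genes, 7803 were so on both arrays and 177 on the control array only. Of the 25 brain markers detected on both arrays, 23 were at least 2-fold lower after senecionine and none was higher (median log2 ratio -2.09, percentile 0.0 of random lists). The lowest of them, named after their values were seen, were the neuropeptide Cck (log2 ratio -4.48 ± 0.24), the neuronal tubulin Tubb3 (-4.32 ± 0.20) and the myelin gene Cldn11 (-4.28 ± 0.31). A further 13 of the 54 were well above background on the senecionine array only and 9 on the control array only. Markers of 9 other tissues, from pancreas to adipose tissue, were well above background on the control array in 15 of 74 cases. In each of these tissues except adipose, more markers were well above background on the senecionine array. With 23 brain markers at least 2-fold lower, the count of lower genes above includes neural genes present on the control array.

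**Figure D3:**
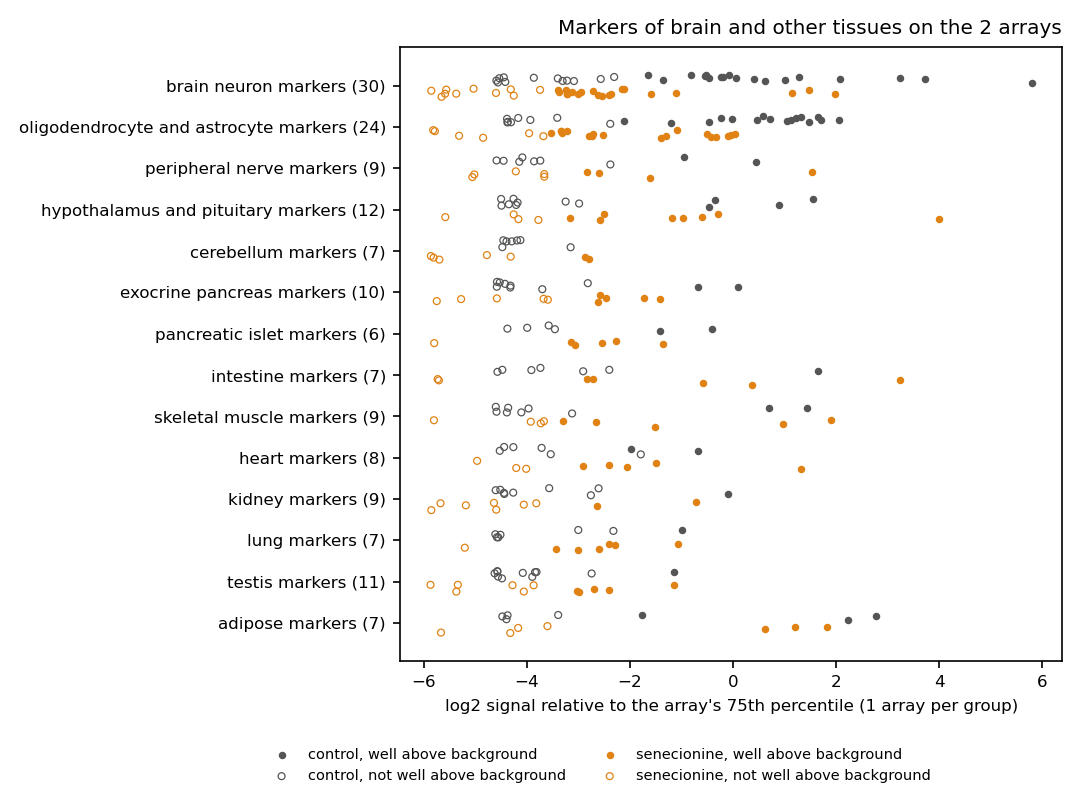
Log2 signal of tissue markers relative to the array's 75th percentile (x axis) on the control array (grey) and the senecionine array (orange), with 1 point per gene, the number of markers in brackets and open points for signals not well above background. Neuron, oligodendrocyte and astrocyte markers reach higher signals on the control array, where 34 of 54 were well above background against 15 of 74 for the 9 tissues from pancreas to adipose. Among all 13667 named genes, 7803 were well above background on both arrays and 177 on the control array only. Detection was more frequent on the senecionine array, with 20 neuron markers against 18 and 18 oligodendrocyte and astrocyte markers against 16. The same held in each of the 9 tissues except adipose.

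A further 2612 genes were well above background on the senecionine array only and 177 on the control array only. Of the 33 lists, the growth hormone and sex-biased list was the only one with members on the control array only, 2 of them. Of the 2612, 319 had a bound of at least 2-fold. The lowest signal called well above background was higher on the control array, so the bounds of genes on that array only largely lie past 2-fold by construction, and the 177 are not set against the 319. The highest bounds on the senecionine array were those of Spp1, Akr1b8 and Cxcl2 given above. On the control array they belonged to Stac3 (at least 83.4-fold lower after senecionine), the neuronal Nrsn1 (at least 34.1-fold) and Asphd2 (at least 33.2-fold). The authors' deposited table lists 4003 probes as higher and 3401 as lower after senecionine.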

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

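The test with 1 signal floor for both arrays was added after the data were first examined, and its repeat on unscaled signals after its result was seen. Data outside the gene comparisons held signal too: among 7282 probes without a gene name that were well above background on both arrays, 600 were at least 2-fold higher and 1434 at least 2-fold lower after senecionine.

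The arrays differed in how many probes they detected. On the senecionine array alone 8774 probes were well above background, against 603 on the control array alone, a ratio of 14.6. A candidate explanation is the higher background noise of the control array, whose threshold for detection lies higher. With 1 signal floor for both arrays the numbers were 2205 and 2163, a ratio of 1.02, but scaling both arrays to their 75th percentile largely holds that ratio near 1. On unscaled signals the numbers were 3651 and 1452, a ratio of 2.51, with the senecionine array the brighter of the pair. Spots for spike-in RNA, which is not a liver transcript, went the same way. Of 320 such spots, 16 were well above background on the control array and 91 on the senecionine array. Liver transcripts alone do not readily account for that, though whether spike-in RNA was added alike is not known here. The shares of noise, brightness and a wider set of transcripts after senecionine cannot be told apart here.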

How the results depend on the processing

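No paired analysis was possible because each group has 1 array, and leaving out the control array leaves no comparison. The 2 main counts, 876 higher and 1379 lower, stayed within 1.5 times under median, quantile and cyclic loess scaling (876 to 982 higher, 1238 to 1379 lower), a signal above the median probe, both probe rules and, chosen after seeing the data, 1 signal floor for both arrays (1151 and 1355) or leaving out markers of other tissues (870 and 1350). These markers do not include the neural genes seen first, such as Mt3 and Mbp, so the 1350 still hold neural genes. Leaving out saturated probes removed none. With normexp correction 613 were higher and 761 lower; its offset of 50 shrinks the ratios of dim genes by construction. Without a filter on dim probes 2394 were higher and 3000 lower, and 2389 were higher with detection on at least 1 array. The authors' values, whose table is not limited to probes detected on both arrays, gave 2032 higher genes, with higher genes 57.8% of the total. At 1.5-fold 1642 were higher and 2424 lower, and at 4-fold 213 and 361. The largest shift of the median gene by a scaling or background choice was 0.13, with normexp. No list median that lay outside the middle 95% of random lists changed sign. The authors' values gave no list medians, since their table holds only probes past 2-fold. Of 141 named genes past 2-fold, 131 stayed so with normexp and 139 with quantile, cyclic loess or the mean of probes. Most of them were picked for large ratios in these data, so their stability says little of other genes past 2-fold. Camk2b reversed, to 0.135, when probes had to exceed the median signal on both arrays, because its other probe then represented it. Signal over background limits genes that are dim on the control array.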

Other observations

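The tests of other tissues, of nerves and of the hepatocyte share were chosen in this form only after their results were seen, as were the use of detection on the control array for the brain explanation and the addition of the zonal lists to the test of scaling. The marker lists of other tissues and of the Y chromosome were written after the data were first examined.

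Y-linked Eif2s3y and Ddx3y were well above background on both arrays, at log2 ratios of -0.12 and -0.03, within their spot error of 0.21. Among markers named after their values were seen, the neuropeptide Npy was higher after senecionine (log2 ratio 2.44 ± 0.20), opposite to most brain markers detected on both arrays, while the adipose markers Cfd and Lpl parted, at -2.14 ± 0.20 and 3.58 ± 0.28. Of 7 cerebellum markers none was well above background on the control array, and of 12 hypothalamus and pituitary markers 4 were.

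The first pattern is the set of neural genes on the control array. The 54 brain markers had a median log2 ratio of -1.73, which includes probes not well above background. Over the 25 detected on both arrays it was -2.09. RNA of brain in the control pool, or on its array, is a candidate explanation. It is left open by 20 of the 54 that were not well above background there, including Gfap, Camk2a and Syt1, which brain holds in abundance; no array here shows whether their probes report brain RNA. A general rise of genes foreign to liver on that array stays open, since the 15 of 74 markers of 9 other tissues that were well above background there went both ways, with a median of -0.62 against -2.55 for the 34 brain markers, and the rest cannot show a rise. Nerves of the liver itself stay open too, since only 2 peripheral nerve markers were well above background there, with a median 2.51 above that of 16 oligodendrocyte and astrocyte markers. An effect of senecionine on these genes in liver was not tested and stays open.

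The second pattern is the lower level of hepatocyte genes. A choice among these scalings is argued against by 7 lists (cytochrome P450, bile acid, urea cycle, secreted protein, coagulation, pericentral and periportal genes). Their highest median under the 3 other scalings was -0.673. Some of these lists share members. Each of the 3 scalings brings the arrays to a common level and moved the median gene by at most 0.069. An offset of all genes between the arrays was therefore not tested. Animals of another sex in the senecionine pool are argued against by the Y-linked genes (median -0.073, where 1 female of 3 would give -0.585). The female-predominant Cyp2c12, at 0.31, cannot decide this, since Cyp2c probes can hybridise to each other's transcripts. A lower share of hepatocyte RNA alone would raise markers of every other cell type alike. Among 7 lists of other cell types, the pair furthest apart was taken. The upper quartile of sinusoidal endothelial markers (0.04) lay 0.575 under the lower quartile of 8 erythrocyte and platelet markers (0.615). The endothelial median lay at percentile 3.5 of random lists. Since the pair was picked for its gap, it argues only weakly against a lower hepatocyte share as the whole cause. A lower share beside a rise of blood cells stays open. A response to senecionine, and differences in feeding, sampling hour or single animals within the pools, stay open, since the design has 1 pool per group.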
